A study of Homo sapiens with 42 samples.

How the data were processed

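RNA was measured by sequencing in 42 libraries of the human lines HEK293T and THP-1. Per the labels' protocols, total RNA was taken with a column kit whose ethanol volumes were changed to retain small RNA. Stranded mRNA libraries were made after poly(A) selection. ASOs and siRNAs were delivered with Lipofectamine RNAiMax and plasmids with another Lipofectamine reagent. Reads were paired, of 151 cycles, from a NovaSeq X Plus. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20, trimmed with Trim Galore and quantified with Salmon against hg38, and DESeq2 was used. The versions of Trim Galore, Salmon and DESeq2 and the authors' transcript annotation are not given in the sources used here. Per the file headers, the authors deposited for each of 194142 transcripts and each library an estimated count, which need not be whole, and a TPM value. Estimated counts were the basis of all tests, and TPM was used only with them to derive each gene's average effective length.

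Transcript identifiers were matched to GENCODE release 29 (GRCh38), which named 158359 of them (81.6%) and 91.1% of the reads, and the estimated counts were summed per gene and rounded to whole numbers, giving 34318 genes, of which 19465 were protein-coding. Transcripts without a match took 8.06% to 9.54% of a library's 32705684 to 52568088 reads and entered neither library sizes nor tests. Salmon divides reads between near-identical transcripts by estimation, so genes with close copies or overlapping genes have less certain values than others, and 69 genes had 0 reads in 1 replicate and at least 5 CPM in another of the same group. Where a group was at 0 reads, a lower bound on the fold was set against a floor of 3 reads per library, which covers counting error only. The bound does not cover reads assigned to other transcripts, among them those without a match. Replicates were 3 per group, and since the labels do not say that they came from separate cultures, p-values measure only the spread between these samples, which may be technical.

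Comparisons, gene lists, the rule for named genes and the alternatives, save those named below, were fixed before the data were examined. Each experiment was fitted by itself with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalization, quasi-likelihood F-test), with Benjamini-Hochberg adjustment over all genes tested and calls at an adjusted p under 0.05. The difference between the POLR3G ASO and siRNA was fitted over the 12 libraries of both experiments. Tests of 31 gene lists used camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 5 tested members, beside a version with the correlation estimated per list and the fry test. For each comparison the named genes are POLR3G, POLR3GL and MAF1, then the 5 called genes with the largest rise and the 5 with the largest fall that had a mean of at least 5 CPM, no overlap between libraries and a standard symbol. The named genes continue with up to 3 called members with the smallest adjusted p of each list that camera called or that had at least 3 called members, taken in order of the list's p up to about 30 genes, and up to 5 genes per direction of each same-direction count. Overlaps were set against independent lists of the same sizes and, for shared controls, against 20 simulations of unchanged groups. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables, figures and the search for seed sites, which tested all 16384 7-mers over 3′ UTRs of at least 50 bases in genes with a mean of at least 5 CPM, for 7-mers in at least 50 genes, against 100 shuffles.

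The test was tried on simulated data drawn from the real means and library sizes with 200 genes changed, 50 at each fold. Of those at 1.25, 1.5, 2 and 4-fold it recovered 66%, 70%, 86% and 100% for the POLR3G ASO, 44%, 86%, 98% and 100% for the POLR3G siRNA, 60%, 74%, 90% and 100% for siE4, 64%, 68%, 88% and 98% for siE6, 60%, 74%, 98% and 100% for siE8, 50%, 76%, 94% and 100% for MAF1 overexpression, 52%, 72%, 92% and 94% for ML-60218, 38%, 76%, 94% and 100% for CHX, 52%, 84%, 92% and 100% for ML-60218 with CHX, 34%, 62%, 74% and 100% for the interaction and 48%, 56%, 76% and 94% for the difference between ASO and siRNA. It called 3 to 15 unchanged genes. Alternatives to the main settings were DESeq2 1.42.0, DESeq2 size factors, no filter on low counts, an adjusted p under 0.01, the replicate number as a block, other sets of libraries in the fit and each library left out in turn. Chosen after seeing the data were an offset for each gene's average effective length (the length offset), a minimum mean of 5 CPM and the removal of the 69 genes above. None of the scalings moved the median log2 fold change of all genes by more than 0.02, and no list called by camera changed the sign of its median under another scaling. Transcripts made by Pol III, splicing and transcript usage were not analysed here, and some genes that met the rule are not reported here.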

Results

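Polyadenylated RNA was sequenced from 42 libraries, 3 for each of 14 groups in 5 experiments, to ask how inhibition of RNA polymerase III (Pol III) bears on the expression of protein-coding genes. Pol III makes tRNAs and other short noncoding RNAs, and its subunit RPC7 exists as paralogs encoded by POLR3G and POLR3GL, while MAF1 is a repressor of Pol III. In HEK293T, a human embryonic kidney line, an antisense oligonucleotide (ASO) against POLR3G was set against a scrambled ASO (200 nM), a POLR3G siRNA against a control siRNA (200 nM), and 3 POLR3GL siRNAs (siE4, siE6 and siE8) against a control siRNA (25 nM), each for 48 h. The fourth experiment compared HEK293T cells overexpressing MAF1 with cells overexpressing eGFP after 48 h. In THP-1, a human monocytic leukaemia line, the Pol III inhibitor ML-60218 (25 uM, 4 h), the translation inhibitor cycloheximide (CHX, 10 ug/ml, 4.5 h) and their combination were used, with DMSO as the control for each agent alone and CHX as the control for the combination. The libraries held 32705684 to 52568088 estimated reads. Products of Pol III were not analysed here, since 0 of the 26 listed transcripts entered the tests.

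The targeted genes were measured in each group, with levels as mean CPM (counts scaled to library size) ± SD and fold changes as log2 ± SE, n = 3 libraries per group. For each gene given as risen or fallen between 2 groups, all 3 libraries of either group lay beyond all 3 of the other. The POLR3G ASO lowered POLR3G (ENSG00000113356, chromosome 5, 90471748 to 90514553, plus strand, GRCh38) from 24.1 ± 3.79 to 8.57 ± 1.95 CPM, 2.81-fold (log2 -1.49 ± 0.16, adjusted p = 3.48e-05). POLR3GL (ENSG00000121851, chromosome 1, 145964702 to 145978848, plus strand) also fell 1.36-fold (log2 -0.44 ± 0.062). MAF1 was at log2 -0.018 ± 0.031 (adjusted p = 0.611), which did not pass the test and changed sign to 0.057 with the length offset. With the POLR3G siRNA, POLR3G fell from 34.4 ± 6.13 to 14.5 ± 2.46 CPM, 2.38-fold (log2 -1.253 ± 0.15, adjusted p = 4.71e-05). In these libraries MAF1 fell further, from 49.96 ± 1.30 to 9.84 ± 0.675 CPM, 5.07-fold (log2 -2.34 ± 0.05), and POLR3GL fell 1.49-fold (log2 -0.57 ± 0.037). MAF1 transcripts hold the 7-mer CCGCAGA, which had the lowest t of all 7-mers in 3′ UTRs with this siRNA (-9.6) and occurs in POLR3G transcripts as well. The 3 POLR3GL siRNAs lowered POLR3GL from 34.1 ± 2.00 CPM to 2.89 ± 0.472 (siE4), 3.36 ± 0.613 (siE6) and 2.61 ± 0.207 (siE8). These values were 11.8-fold (log2 -3.56 ± 0.14), 10.2-fold (log2 -3.35 ± 0.13) and 13.1-fold (log2 -3.71 ± 0.14) lower.

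POLR3G fell with these siRNAs as well, 1.80-fold (log2 -0.84 ± 0.079) with siE4, 1.48-fold (log2 -0.56 ± 0.078) with siE6 and 1.91-fold (log2 -0.93 ± 0.08) with siE8. MAF1 fell 1.13-fold (log2 -0.18 ± 0.057, adjusted p = 0.0174) with siE4, a call that was lost at adjusted p = 0.0749 to 0.0818 without siE4 replicate 2 and 25 nM control siRNA replicate 2. For MAF1 the range over all alternatives was 0.0031 to 0.0818. With siE6 and siE8, MAF1 was at log2 0.086 ± 0.056 (adjusted p = 0.202) and 0.078 ± 0.056 (adjusted p = 0.261) and did not pass. Without control siRNA replicate 2 it was called higher (adjusted p = 0.0152 and 0.0221, over ranges of 0.0152 to 0.632 and 0.0221 to 0.746). Overexpression raised MAF1 from 41.4 ± 1.16 to 3090 ± 217 CPM, 74.7-fold (log2 6.22 ± 0.063), with POLR3G at log2 -0.20 ± 0.097 (adjusted p = 0.548) and POLR3GL at -0.034 ± 0.044 (adjusted p = 0.828). THP-1 cells held POLR3G at 1.21 ± 1.03 CPM in DMSO, and its direction under each treatment changed when 1 library was left out, as described for the processing alternatives. POLR3GL fell 1.11-fold (log2 -0.15 ± 0.035, adjusted p = 0.0115) with ML-60218, a call lost at adjusted p = 0.0517 with the length offset and 0.0526 to 0.0541 without DMSO replicate 1 and ML-60218 replicate 2. For POLR3GL the range over all alternatives was 0.00867 to 0.0541. With ML-60218 under CHX it was at log2 -0.031 ± 0.034 (adjusted p = 0.609). CHX lowered MAF1 1.38-fold (log2 -0.46 ± 0.031) and raised POLR3GL 1.14-fold (log2 0.19 ± 0.035). MAF1 was at log2 0.035 ± 0.031 (adjusted p = 0.51) with ML-60218 and -0.066 ± 0.032 (adjusted p = 0.194) with ML-60218 under CHX.

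**Figure D1:**
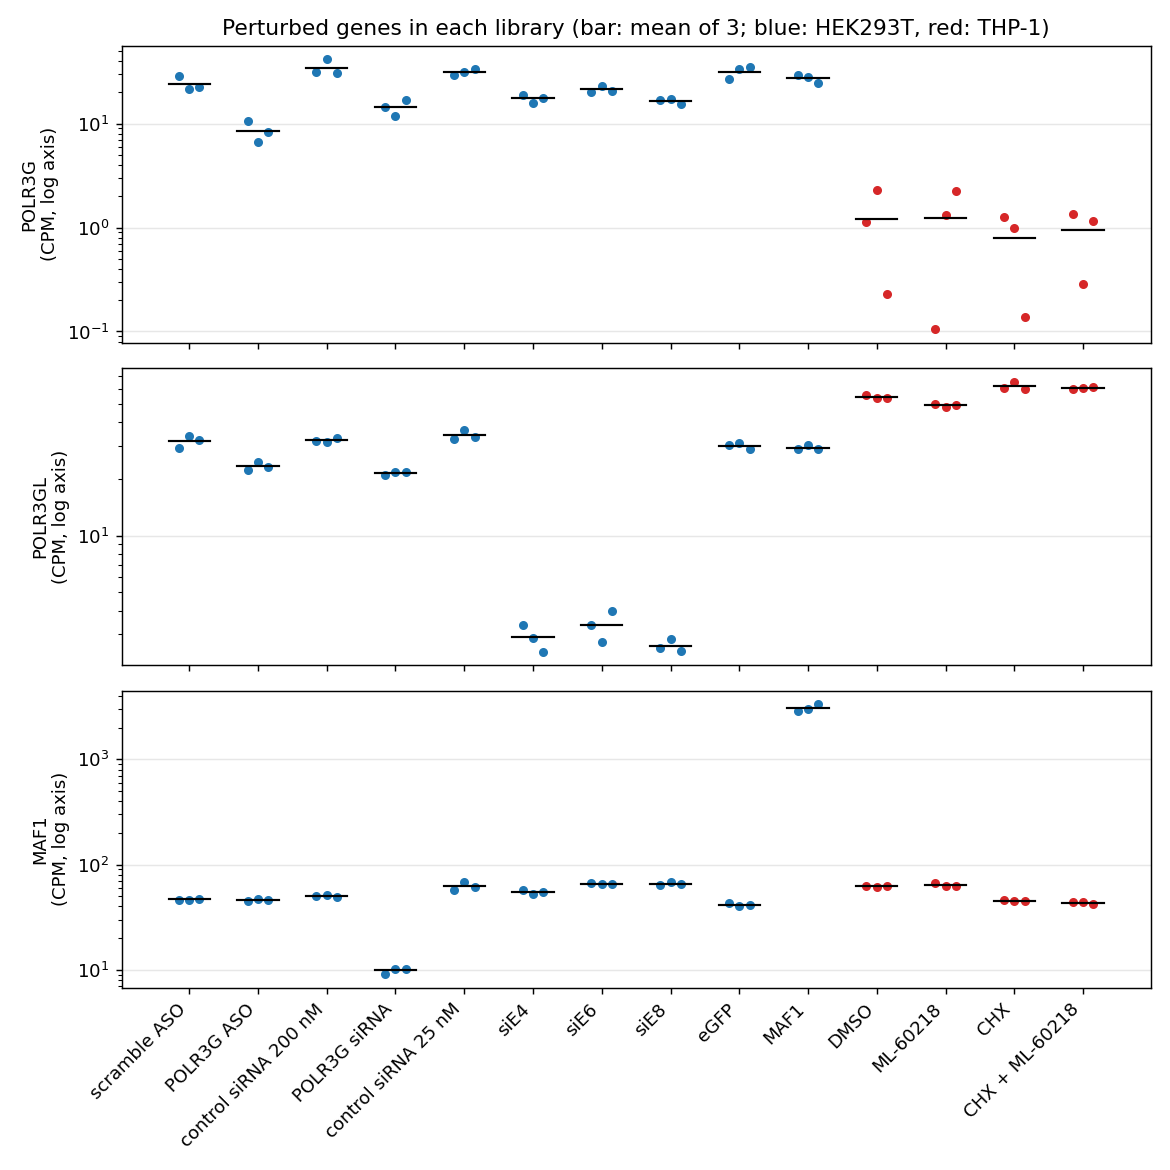
CPM of POLR3G, POLR3GL and MAF1 on a log axis in the 14 groups, with a point for each library and a bar at the mean of 3 libraries, HEK293T in blue and THP-1 in red. POLR3GL lies between 2.61 and 3.36 CPM with its 3 siRNAs, and MAF1 lies at 3090 CPM on overexpression and at 9.84 CPM with the POLR3G siRNA.

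The POLR3G ASO comparison asked which genes respond to depletion of the POLR3G transcript in HEK293T cells. Of 17098 genes tested, 11713 were called at an adjusted p under 0.05, 5890 higher and 5823 lower, and 2498 of the rises but 214 of the falls exceeded 2-fold. The pregnancy-specific glycoprotein genes PSG5 and PSG4, members of a family with near-identical copies whose reads are uncertain, were higher by 222-fold (log2 7.79 ± 0.29, adjusted p = 9.37e-08) and 25.7-fold (log2 4.68 ± 0.16, adjusted p = 5.96e-08). The pseudogene SSBL4P rose 20.3-fold (log2 4.35 ± 0.17), the olfactory receptor gene OR5AU1 17.3-fold (log2 4.11 ± 0.13) and GARIN4 15.4-fold (log2 3.95 ± 0.23). Among the falls, STUM fell 6.39-fold (log2 -2.67 ± 0.084), MED12, a subunit of the Mediator kinase module, 3.86-fold (log2 -1.95 ± 0.09), and KMT2D, a histone H3 lysine methyltransferase, 7.07-fold (log2 -2.82 ± 0.18). With the length offset KMT2D was at log2 0.007 (adjusted p = 0.952, over a range of 7.2e-31 to 0.952 for its alternatives). SMURF1, a ubiquitin ligase gene, is among 69 switching genes, with 0 reads in 1 replicate and at least 5 CPM in another of some group. It fell 4.41-fold (log2 -2.14 ± 0.77, adjusted p = 0.0332), from 16.1 ± 2.91 to 3.69 ± 4.55 CPM, and lost its call at adjusted p = 0.314 with DESeq2, 0.0683 with all HEK293T libraries in the fit and 0.0502 to 0.111 without POLR3G ASO replicate 2 and scramble ASO replicate 1 or 2 or 3. For SMURF1 the range over all alternatives was 0.00321 to 0.314. EHMT2, another histone methyltransferase gene, fell 3.78-fold (log2 -1.92 ± 0.67, adjusted p = 0.0283), to 8.58 ± 10.9 CPM, and lost its call at adjusted p = 0.0503 to 0.0918 without POLR3G ASO replicate 2 or 3 and scramble ASO replicate 1 or 2 or 3. For EHMT2 the range over all alternatives was 1.19e-05 to 0.0918.

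In poly(A) RNA, 24 of 26 tested replication-dependent histone genes rose and 0 fell (25 and 0 adjusted over the list alone). Camera gave adjusted p = 6.08e-06 (0.158 with an estimated correlation). H2AC6 rose 3.81-fold (log2 1.93 ± 0.13), H2BC5 3.14-fold (log2 1.65 ± 0.12) and H4C8 3.31-fold (log2 1.73 ± 0.12), with a highest adjusted p = 3.13e-06. Among ribosomal protein genes, many of which have pseudogene copies that can share their reads, 62 of 77 tested fell and 3 rose (62 and 3 adjusted over the list alone), with camera adjusted p = 6.08e-06, adjusted p = 0.337 with an estimated correlation. RPL3 fell 1.38-fold (log2 -0.47 ± 0.017), with adjusted p = 8.62e-08, and the elongation factor gene EEF1A1 fell 1.16-fold (log2 -0.22 ± 0.018). Immediate early genes numbered 34 in the test, of which 26 rose and 2 fell (26 and 2 adjusted over the list alone), at camera adjusted p = 2.32e-05, adjusted p = 0.158 with an estimated correlation. DUSP1 rose 2.43-fold (log2 1.28 ± 0.035), KLF6 2.05-fold (log2 1.04 ± 0.029) and IER2 1.90-fold (log2 0.93 ± 0.039), with a highest adjusted p = 1.72e-07. 31 of 42 tested ribosome biogenesis genes rose and 5 fell (31 and 5 adjusted over the list alone), with camera adjusted p = 5.99e-05, adjusted p = 0.297 with an estimated correlation. WDR74 rose 5.72-fold (log2 2.52 ± 0.041), PPAN 1.49-fold (log2 0.57 ± 0.025) and MRTO4 1.63-fold (log2 0.71 ± 0.032), with a highest adjusted p = 2.79e-07.

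G2/M genes fell in 29 of 35 tested cases and rose in 2 (29 and 2 adjusted over the list alone), at camera adjusted p = 6.44e-05, adjusted p = 0.158 with an estimated correlation. TPX2 fell 1.43-fold (log2 -0.52 ± 0.019), CCNB2 1.40-fold (log2 -0.48 ± 0.031) and HMGB2 1.21-fold (log2 -0.28 ± 0.021), with a highest adjusted p = 4.35e-06. Among genes encoded by mitochondrial DNA, 13 of 13 tested fell and 0 rose (13 and 0 adjusted over the list alone), with camera adjusted p = 0.000119, adjusted p = 0.357 with an estimated correlation. MT-ND2 fell 1.29-fold (log2 -0.36 ± 0.023) and MT-CYB 1.39-fold (log2 -0.47 ± 0.03), with a highest adjusted p = 1.72e-06. tRNA synthetase genes numbered 20 in the test, of which 15 fell and 0 rose (16 and 0 adjusted over the list alone), at camera adjusted p = 0.000144, adjusted p = 0.158 with an estimated correlation. The amino acid transporter genes SLC7A1 and SLC38A2 fell 1.58-fold (log2 -0.66 ± 0.022) and 1.51-fold (log2 -0.60 ± 0.027), and MCL1, which encodes an antiapoptotic protein, rose 1.26-fold (log2 0.33 ± 0.019). 10 of 15 tested monocyte and macrophage marker genes rose and 2 fell (10 and 2 adjusted over the list alone), with camera adjusted p = 0.0246, adjusted p = 0.297 with an estimated correlation. Targets of ATF4 in the integrated stress response fell in 17 of 29 tested cases and rose in 8 (17 and 8 adjusted over the list alone), at camera adjusted p = 0.0555, adjusted p = 0.409 with an estimated correlation, which did not pass. In the same libraries the summed level of olfactory receptor genes was 603.7 ± 24.3 CPM (SD, n = 3) against 190 ± 6 with the scrambled ASO, and the share of reads on mitochondrial genes was 7.777% ± 0.105 against 9.543% ± 0.418. Among genes with a mean of at least 5 CPM, 8357 were called and 37.0% of them were higher, against 50.3% over all genes tested.

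The POLR3G siRNA addressed the same target by another agent. Of 15423 genes tested, 11551 were called, 5674 higher and 5877 lower, and here 906 rises and 1465 falls exceeded 2-fold. SCG3, a secretory granule protein of neuroendocrine cells, rose 123-fold (log2 6.94 ± 0.17, adjusted p = 2.18e-09), and UNC13A, which primes synaptic vesicles, 23.0-fold (log2 4.52 ± 0.066). RAB3C rose 14.6-fold (log2 3.87 ± 0.086), the sodium channel subunit SCN3B 12.2-fold (log2 3.60 ± 0.29) and synaptophysin (SYP) 11.2-fold (log2 3.49 ± 0.036). MYO19, VPS52 and BFAR, a switching gene, had no reads in any POLR3G siRNA library. They were at least 461, 248 and 175-fold lower against a floor of 3 reads per library. Assignment of reads to other transcripts was tested for no gene at 0 reads. CHAC1, a glutathione-degrading enzyme induced by ATF4, fell 17.5-fold (log2 -4.13 ± 0.078, adjusted p = 7.02e-10) and INHBE 15.2-fold (log2 -3.92 ± 0.15). Among ATF4 targets, 28 of 29 tested fell and 0 rose (28 and 0 adjusted over the list alone), with camera adjusted p = 1.45e-09, adjusted p = 0.374 with an estimated correlation. ASNS, asparagine synthetase, fell 5.55-fold (log2 -2.47 ± 0.032), PSAT1, an enzyme of serine synthesis, 3.79-fold (log2 -1.92 ± 0.018) and SLC7A5 2.52-fold (log2 -1.33 ± 0.019), with a highest adjusted p = 1.64e-10.

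Ribosome biogenesis genes numbered 42 in the test, of which 38 rose and 1 fell (38 and 1 adjusted over the list alone), at camera adjusted p = 8.8e-10, adjusted p = 0.374 with an estimated correlation. DDX10 rose 3.14-fold (log2 1.65 ± 0.026), UTP15 2.31-fold (log2 1.21 ± 0.024) and MRTO4 2.08-fold (log2 1.06 ± 0.023), with a highest adjusted p = 1.31e-09. 33 of 42 tested nuclear genes of oxidative phosphorylation rose and 4 fell (33 and 4 adjusted over the list alone), with camera adjusted p = 0.000158, adjusted p = 0.446 with an estimated correlation. ATP5F1C rose 1.49-fold (log2 0.57 ± 0.019), ATP5MC1 1.69-fold (log2 0.76 ± 0.031) and ATP5MC3 1.45-fold (log2 0.54 ± 0.022), with a highest adjusted p = 4.5e-08. Genes of splicing and mRNA 3′ end processing rose in 29 of 36 tested cases and fell in 6 (30 and 6 adjusted over the list alone), at camera adjusted p = 0.000506, adjusted p = 0.446 with an estimated correlation. HNRNPU rose 1.68-fold (log2 0.75 ± 0.017), TRA2B 1.64-fold (log2 0.71 ± 0.017) and HNRNPC 1.40-fold (log2 0.49 ± 0.016), with a highest adjusted p = 1.1e-08. Among heat shock and chaperone genes, 15 of 18 tested rose and 3 fell (15 and 3 adjusted over the list alone), with camera adjusted p = 0.00128, adjusted p = 0.446 with an estimated correlation. DNAJA1 rose 3.38-fold (log2 1.76 ± 0.022), HSP90AA1 2.72-fold (log2 1.44 ± 0.019) and HSPH1 2.55-fold (log2 1.35 ± 0.025), with a highest adjusted p = 5.9e-10. Cholesterol synthesis genes numbered 24 in the test, of which 17 fell and 3 rose (17 and 3 adjusted over the list alone), at camera adjusted p = 0.00267, adjusted p = 0.374 with an estimated correlation. SREBF2, which encodes the main activator of these genes, fell 2.21-fold (log2 -1.15 ± 0.027), with adjusted p = 1.83e-09. 14 of 18 tested genes of Pol III subunits rose and 4 fell (14 and 4 adjusted over the list alone), with camera adjusted p = 0.0135, adjusted p = 0.446 with an estimated correlation. The 4 falls include POLR3G and POLR3GL. POLR3E, another subunit gene chosen after its values were seen, fell from 75.09 to 32.77 CPM (log2 -1.198 ± 0.065) against log2 -0.16 with the ASO.

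Both POLR3G agents were compared directly, as the log2 fold change with the ASO minus that with the siRNA, each against its own control. Of 17489 genes tested, 11679 differed, 5909 with a higher value for the ASO and 5770 with a lower one. At a mean of at least 5 CPM, 8966 differed and 41.5% of them had a higher value for the ASO, against 50.6% over all genes tested. SCG3 had a lower value with the ASO, by 88.7-fold (log2 -6.47 ± 0.28, adjusted p = 3.75e-10), as did RAB3C, by 23.0-fold (log2 -4.53 ± 0.15), UNC13A, by 22.2-fold (log2 -4.47 ± 0.15), and STAMBP, which encodes a deubiquitinase, by 24.4-fold (log2 -4.61 ± 0.98). ASXL3 had a higher value with the ASO, by 45.7-fold (log2 5.51 ± 1.38), as did INHBE, by 34.2-fold (log2 5.10 ± 0.22), and OR5AU1, by 22.1-fold (log2 4.47 ± 0.28). MAF1 differed by 4.91-fold (log2 2.29 ± 0.059, adjusted p = 3.31e-12). The SD exceeded the mean for ASXL3 with the ASO (12.1 ± 16.3 CPM) and STAMBP with the scrambled ASO (4.08 ± 4.32 CPM). Both folds are uncertain. BTBD7 and ZNHIT3 ranked high too, but are switching genes with a group at 0 reads, so no fold is given. 24 of 29 tested ATF4 targets had a higher value with the ASO and 1 a lower one (24 and 1 adjusted over the list alone), at camera adjusted p = 2.02e-07, adjusted p = 0.198 with an estimated correlation. Their median log2 fold change was below 0 with both agents, at -0.50 with the ASO and -1.22 with the siRNA. DDIT4 differed by 5.62-fold (log2 2.49 ± 0.058), STC2 3.31-fold (log2 1.73 ± 0.043) and CEBPG 2.94-fold (log2 1.55 ± 0.04), with a highest adjusted p = 3.18e-12. Nuclear genes of oxidative phosphorylation had a higher value with the ASO in 1 cases and a lower one in 37, of 42 tested (1 and 37 adjusted over the list alone), at camera adjusted p = 1.91e-08, adjusted p = 0.198 with an estimated correlation. ATP5F1C differed by 1.69-fold (log2 -0.76 ± 0.032), ATP5F1B 1.41-fold (log2 -0.49 ± 0.022) and COX6C 1.93-fold (log2 -0.95 ± 0.044), with a highest adjusted p = 7.02e-10.

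G2/M genes had a higher value with the ASO in 2 cases and a lower one in 30, of 35 tested (2 and 30 adjusted over the list alone), at camera adjusted p = 6.7e-08, adjusted p = 0.0381 with an estimated correlation, the only list in the 11 comparisons that passed with an estimated correlation. TPX2 differed by 1.66-fold (log2 -0.73 ± 0.027), TOP2A 1.78-fold (log2 -0.83 ± 0.032) and KIF11 2.47-fold (log2 -1.30 ± 0.059), with a highest adjusted p = 4.68e-10. HSP90AA1, a cytosolic chaperone, differed by 2.85-fold (log2 -1.51 ± 0.033) and DNAJA1 2.79-fold (log2 -1.48 ± 0.036), with a highest adjusted p = 2e-12. In the 15228 genes tested with both agents, 5207 were called in the same direction, 2076 higher and 3131 lower, where independent lists of these sizes would share 3851. Another 2710 were called in opposite directions against 3831 for independent lists. HOXA3 rose 4.03-fold (log2 2.01 ± 0.057) with the ASO and 2.75-fold (log2 1.46 ± 0.045) with the siRNA and ZNF503 2.37-fold (log2 1.247 ± 0.034) and 6.56-fold (log2 2.71 ± 0.022). EIF5 rose 1.63-fold (log2 0.70 ± 0.019) and 2.44-fold (log2 1.29 ± 0.02) and the cell cycle inhibitor gene CDKN2B 2.47-fold (log2 1.31 ± 0.036) and 1.90-fold (log2 0.92 ± 0.027). EXOC4, a subunit of the exocyst, fell 2.48-fold (log2 -1.31 ± 0.04) and 1.68-fold (log2 -0.74 ± 0.027). The kinase gene RPS6KA2 fell 2.66-fold (log2 -1.41 ± 0.046) and 3.71-fold (log2 -1.89 ± 0.039). Over 11022 genes, which are not independent replicates, the log2 fold changes of both agents had Pearson's r = 0.324 and Spearman's rho = 0.355.

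The POLR3GL siRNAs each addressed the paralog of POLR3G with a different sequence. With siE4, 8553 of 15573 genes tested were called, 4084 higher and 4469 lower. The adaptor gene DOK3 rose 6.05-fold (log2 2.60 ± 0.17, adjusted p = 4.16e-08) and TMEFF1 4.18-fold (log2 2.06 ± 0.18). The lipid kinase gene PIP4K2A rose 4.11-fold (log2 2.04 ± 0.05). NTAN1, a switching gene, rose 6.35-fold (log2 2.67 ± 0.68). RDM1 fell 9.99-fold (log2 -3.32 ± 0.90, adjusted p = 0.00879) and CHAC1 9.69-fold (log2 -3.28 ± 0.12). The G protein subunit gene GNB1 fell 5.01-fold (log2 -2.33 ± 0.071) and ferrochelatase (FECH) 4.68-fold (log2 -2.23 ± 0.21). 24 of 29 tested ATF4 targets fell and 1 rose (24 and 1 adjusted over the list alone), with camera adjusted p = 1.45e-09, adjusted p = 0.523 with an estimated correlation. PSAT1 fell 4.64-fold (log2 -2.21 ± 0.072) and SLC7A5 3.43-fold (log2 -1.78 ± 0.06), with a highest adjusted p = 1.36e-10. Ribosomal protein genes rose in 57 of 77 tested cases and fell in 1 (60 and 2 adjusted over the list alone), at camera adjusted p = 1.23e-08, adjusted p = 0.852 with an estimated correlation. RPL34 rose 1.61-fold (log2 0.69 ± 0.053), RPL15 1.48-fold (log2 0.56 ± 0.055) and RPS27A 1.42-fold (log2 0.51 ± 0.051), with a highest adjusted p = 2.09e-06. Among G2/M genes, 26 of 35 tested rose and 3 fell (26 and 3 adjusted over the list alone), with camera adjusted p = 3.49e-05, adjusted p = 0.852 with an estimated correlation. BUB1 rose 1.44-fold (log2 0.53 ± 0.042), BIRC5 1.46-fold (log2 0.55 ± 0.047) and ANLN 1.32-fold (log2 0.40 ± 0.035), with a highest adjusted p = 6.25e-07. Genes encoded by mitochondrial DNA numbered 13 in the test, of which 13 rose and 0 fell (13 and 0 adjusted over the list alone), at camera adjusted p = 0.00536, adjusted p = 0.852 with an estimated correlation. MT-ND3 rose 1.69-fold (log2 0.76 ± 0.14), MT-ND1 1.94-fold (log2 0.95 ± 0.19) and MT-CYB 1.84-fold (log2 0.88 ± 0.18), with a highest adjusted p = 0.00119. Between replicates, the chi-square per degree of freedom was 17.08 to 30.13 in the 25 nM controls, 5.87 to 10.23 with siE4, 8.58 to 20.05 with siE6 and 5.61 to 13.22 with siE8. Ribosomal protein genes took 8.19% to 9.22% of reads in these controls, 9.01% to 9.76% with siE4 and 9.62% to 9.78% with siE6. Mitochondrial genes took 2.75% to 4.99% in the controls, 5.48% to 6.20% with siE4 and 4.37% to 6.22% with siE6, so that some of these ranges overlap. 18 of 29 tested glycolysis and hypoxia genes fell and 5 rose (18 and 5 adjusted over the list alone), with camera adjusted p = 0.00536, adjusted p = 0.852 with an estimated correlation. HK1, a hexokinase, fell 4.27-fold (log2 -2.09 ± 0.051), NDRG1 2.89-fold (log2 -1.53 ± 0.084) and HK2 2.72-fold (log2 -1.44 ± 0.084), with a highest adjusted p = 1.47e-08.

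With siE6, 9817 of the 15573 genes were called, 4862 higher and 4955 lower. FAM156B rose 7.72-fold (log2 2.95 ± 0.71, adjusted p = 0.00274) and netrin 1 (NTN1) 5.29-fold (log2 2.40 ± 0.062). The histone gene HIST2H2AA3, 1 of a pair of near-identical copies and of the 69 switching genes, was at least 263-fold higher. RDM1 was at least 140-fold lower. KRCC1 fell 9.09-fold (log2 -3.18 ± 0.088), UBE2QL1 7.36-fold (log2 -2.88 ± 0.11) and JDP2 6.46-fold (log2 -2.69 ± 0.12). Ribosomal protein genes rose in 62 of 77 tested cases and fell in 2 (64 and 2 adjusted over the list alone), at camera adjusted p = 1.53e-07, adjusted p = 0.719 with an estimated correlation. RPL34 rose 1.72-fold (log2 0.78 ± 0.053), RPL15 1.54-fold (log2 0.62 ± 0.055) and RPS27A 1.46-fold (log2 0.54 ± 0.051), with a highest adjusted p = 7.59e-07. Among ATF4 targets, 21 of 29 tested fell and 3 rose (21 and 3 adjusted over the list alone), with camera adjusted p = 4.38e-05, adjusted p = 0.61 with an estimated correlation. CHAC1 fell 6.41-fold (log2 -2.68 ± 0.12) and SLC7A11 3.19-fold (log2 -1.67 ± 0.075), with a highest adjusted p = 9.49e-10. P53 targets numbered 25 in the test, of which 18 rose and 4 fell (18 and 4 adjusted over the list alone), at camera adjusted p = 0.000664, adjusted p = 0.6 with an estimated correlation. TP53INP1 rose 3.05-fold (log2 1.61 ± 0.061), CDKN1A, a cell cycle inhibitor, 2.59-fold (log2 1.37 ± 0.058) and AEN 2.18-fold (log2 1.13 ± 0.052), with a highest adjusted p = 1.13e-09.

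14 of 18 tested heat shock and chaperone genes rose and 2 fell (15 and 2 adjusted over the list alone), with camera adjusted p = 0.0018, adjusted p = 0.682 with an estimated correlation. HSP90AA1 rose 2.13-fold (log2 1.09 ± 0.054), DNAJA1 1.87-fold (log2 0.90 ± 0.052) and DNAJB1 1.78-fold (log2 0.83 ± 0.058), with a highest adjusted p = 5.35e-08. Cholesterol synthesis genes rose in 16 of 24 tested cases and fell in 3 (16 and 3 adjusted over the list alone), at camera adjusted p = 0.00228, adjusted p = 0.6 with an estimated correlation. LSS rose 1.75-fold (log2 0.81 ± 0.043) and DHCR7 1.74-fold (log2 0.80 ± 0.05), with a highest adjusted p = 1.68e-08. Among tRNA processing genes, 29 of 40 tested rose and 7 fell (29 and 7 adjusted over the list alone), with camera adjusted p = 0.00315, adjusted p = 0.682 with an estimated correlation. RTCB, the tRNA ligase, rose 1.98-fold (log2 0.99 ± 0.051), TRMT10C 1.55-fold (log2 0.63 ± 0.049) and WDR4 1.65-fold (log2 0.72 ± 0.059), with a highest adjusted p = 2.25e-07. Fibroblast and epithelial marker genes numbered 11 in the test, of which 8 fell and 1 rose (8 and 1 adjusted over the list alone), at camera adjusted p = 0.0399, adjusted p = 0.6 with an estimated correlation.

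With siE8, 8985 of the 15573 genes were called, 4530 higher and 4455 lower. Synaptophysin (SYP) rose 8.70-fold (log2 3.12 ± 0.088, adjusted p = 1.96e-11) and the potassium channel gene KCNC1 7.91-fold (log2 2.98 ± 0.16). The presynaptic scaffold gene BSN rose 5.34-fold (log2 2.42 ± 0.12) and NTAN1, one of the switching genes, 5.91-fold (log2 2.56 ± 0.68). CSRNP3 rose 5.53-fold (log2 2.47 ± 0.56) and was at log2 0.20 with the length offset (adjusted p = 0.729, over a range of 0.000155 to 0.729). REEP3 fell 8.44-fold (log2 -3.08 ± 0.072, adjusted p = 5.95e-12) and NBEA 6.85-fold (log2 -2.78 ± 0.43). The netrin receptor gene UNC5C fell 6.47-fold (log2 -2.69 ± 0.097) and NCEH1 5.80-fold (log2 -2.54 ± 0.06). 27 of 35 tested DNA replication genes rose and 2 fell (27 and 2 adjusted over the list alone), with camera adjusted p = 3.86e-05, adjusted p = 0.76 with an estimated correlation. RFC4 rose 1.65-fold (log2 0.72 ± 0.032), GINS3 1.70-fold (log2 0.77 ± 0.044) and E2F1 1.90-fold (log2 0.92 ± 0.053), with a highest adjusted p = 9.15e-09. Ribosome biogenesis genes rose in 22 of 42 tested cases and fell in 4 (23 and 4 adjusted over the list alone), at camera adjusted p = 0.00599, adjusted p = 0.76 with an estimated correlation. DDX10 rose 2.29-fold (log2 1.198 ± 0.041), GRWD1 by log2 1.14 ± 0.049 and RRS1 2.00-fold (log2 1.00 ± 0.066), with a highest adjusted p = 3.32e-08. In poly(A) RNA, 12 of 21 tested histone genes rose and 0 fell (13 and 0 adjusted over the list alone). Camera gave adjusted p = 0.0185 (0.76 with an estimated correlation). H2AC6 rose 3.44-fold (log2 1.78 ± 0.16), H3C10 3.10-fold (log2 1.63 ± 0.17) and H2BC5 1.73-fold (log2 0.79 ± 0.10), with a highest adjusted p = 1.7e-05. ATF4 targets numbered 29 in the test, of which 9 rose and 9 fell (9 and 9 adjusted over the list alone), at camera adjusted p = 0.889, adjusted p = 0.99 with an estimated correlation.

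Direct tests between the POLR3GL siRNAs called 10085 genes between siE4 and siE6, 9806 between siE4 and siE8 and 9999 between siE6 and siE8. In all 3 comparisons 2303 genes were called in the same direction, 1231 higher and 1072 lower, where independent lists would share 778 and simulated unchanged groups set against the same controls shared 0. The 3 control libraries are too few to be split, so part of the excess can come from them. WDR1, an actin-disassembly factor, rose 3.62-fold (log2 1.86 ± 0.042) with siE4, 3.43-fold (log2 1.78 ± 0.041) with siE6 and 3.57-fold (log2 1.84 ± 0.042) with siE8. MCL1 rose 2.85-fold (log2 1.51 ± 0.036), 3.65-fold (log2 1.87 ± 0.036) and 2.77-fold (log2 1.47 ± 0.036). WWTR1, a transcriptional coactivator of the Hippo pathway, rose 3.30-fold (log2 1.72 ± 0.044), 3.95-fold (log2 1.98 ± 0.044) and 2.94-fold (log2 1.55 ± 0.044). The matrix metalloproteinase gene MMP2 fell 3.02-fold (log2 -1.60 ± 0.094), 5.87-fold (log2 -2.55 ± 0.099) and 3.68-fold (log2 -1.88 ± 0.095). CLU fell 2.02-fold (log2 -1.013 ± 0.057), 2.56-fold (log2 -1.35 ± 0.058) and 1.85-fold (log2 -0.89 ± 0.057). Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.283 (siE4 and siE6), 0.274 (siE4 and siE8) and 0.363 (siE6 and siE8). The means in the same simulation were 0.532, 0.512 and 0.498. Their covariances were 0.0707, 0.065 and 0.101 against simulated means of 0.00874, 0.00839 and 0.00795, leaving differences of 0.062, 0.0566 and 0.0935. The limits of the simulation hold for these differences too.

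Over the 6 HEK293T perturbations, 3525 of 14993 genes tested in all were called in the same direction in at least 4 comparisons, 1584 higher and 1941 lower, where independent lists would give 1198. Part of that excess can come from the controls the 3 POLR3GL siRNAs share. In 5 comparisons 364 genes were higher and 516 lower. By contrast 0 genes were called in all 6 by edgeR, where MAF1 overexpression gave 6 calls (36 by DESeq2). In the other 5 the homeobox gene HOXA5 rose 1.49 to 7.88-fold, MTRF1L 1.40 to 3.23-fold, LYSMD3 1.36 to 2.08-fold and MCL1 1.26 to 3.65-fold. There SLC38A2, a glutamine transporter gene, fell 1.51 to 2.05-fold and MTHFD1L, a mitochondrial enzyme of folate metabolism, 1.38 to 2.10-fold. The collagen receptor gene DDR2 fell 1.52 to 2.87-fold there, BCHE 1.60 to 2.97-fold and CHAC1 2.29 to 17.5-fold.

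Overexpression of MAF1 asked what a repressor of Pol III does to mRNA levels. Of 15543 genes tested, 6 were called, 5 higher and 1 lower, with 1493 genes at an unadjusted p under 0.05 and 36 calls by DESeq2. It gave 2 calls without MAF1 replicate 2 and 3 without MAF1 replicate 3. Besides MAF1 itself, PSAT1 rose 1.18-fold (log2 0.24 ± 0.028, adjusted p = 0.0407) and lost its call at adjusted p = 0.172 with all HEK293T libraries in the fit, 0.128 with the length offset, 0.174 with the replicate block and 0.111 to 0.375 without MAF1 replicate 1 or 2 and eGFP replicate 1 or 2 or 3. For PSAT1 the range over all alternatives was 4.38e-10 to 0.375. RRN3, an initiation factor of RNA polymerase I and one of the switching genes, was at least 182-fold higher, at 14.61 CPM against no reads with eGFP. It lost its call at adjusted p = 0.444 with all HEK293T libraries in the fit. For RRN3 the range over all alternatives was 1.21e-18 to 0.444. DECR2, a peroxisomal enzyme of fatty acid oxidation, was at least 35.8-fold lower and lost its call at adjusted p = 0.484 with all HEK293T libraries in the fit and 0.0691 to 0.129 without MAF1 replicate 2 or 3 and eGFP replicate 1. For DECR2 the range over all alternatives was 0.000136 to 0.484. The other calls lie outside the rule for named genes and were chosen after their values were seen. GARIN1A was at 1.45 ± 0.163 CPM against 0.0364 ± 0.0317 (adjusted p = 0.00613), and ENSG00000284976 was at 1.38 ± 0.365 CPM against no reads with eGFP. Genes that moved together in the other HEK293T comparisons had values of log2 -0.029 ± 0.029 (adjusted p = 0.758) for MCL1, 0.20 ± 0.042 (adjusted p = 0.37) for HOXA5, 0.073 ± 0.038 (adjusted p = 0.563) for SLC38A2 and 0.40 ± 0.11 (adjusted p = 0.409) for CHAC1, none of which passed. DDR2 and EIF5 were at log2 0.23 ± 0.033 (adjusted p = 0.173) and -0.17 ± 0.03 (adjusted p = 0.243), opposite to their direction in the other 5 comparisons. DESeq2 called both (adjusted p = 1.36e-05 for DDR2 and 0.000146 for EIF5), and DDR2 was also called without the filter (adjusted p = 0.0342), over ranges of 1.36e-05 to 0.581 and 0.000146 to 0.709 for all alternatives. 0 of 77 tested ribosomal protein genes rose and 0 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 1.42e-10, adjusted p = 0.825 with an estimated correlation, at a median log2 of 0.064. The fry test, which asks whether a set's genes move on balance one way without comparing them with other genes, gave these genes an adjusted p = 0.472. Nuclear genes of oxidative phosphorylation rose in 0 of 42 tested cases and fell in 0 (0 and 0 adjusted over the list alone), at camera adjusted p = 3.27e-05, adjusted p = 0.825 with an estimated correlation. Among ribosome biogenesis genes, 1 of 42 tested rose and 0 fell (1 and 7 adjusted over the list alone), with camera adjusted p = 0.000621, adjusted p = 0.328 with an estimated correlation, a call of lower members with a median of -0.048 but a mean of 0.23. ATF4 targets numbered 29 in the test, of which 1 rose and 0 fell (9 and 2 adjusted over the list alone), at camera adjusted p = 0.0196, adjusted p = 0.825 with an estimated correlation.

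**Figure D2:**
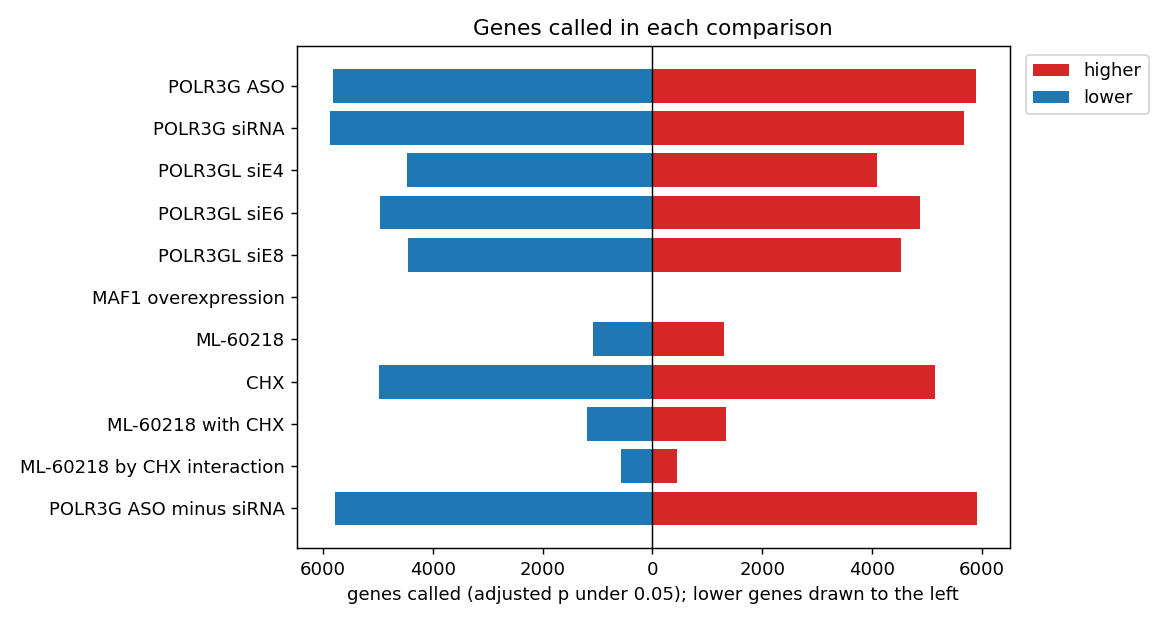
Genes called at an adjusted p under 0.05 in 11 comparisons, with bars for genes called higher (red, to the right) and lower (blue, to the left) on an axis of number of genes. Counts range from 6 for MAF1 overexpression to 11713 for the POLR3G ASO.

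In THP-1 cells, ML-60218 was given for 4 h to follow the early response to Pol III inhibition. Of 15327 genes tested, 2380 were called, 1300 higher and 1080 lower, and 1520 were called without ML-60218 replicate 2. PDK4, a kinase that shuts pyruvate out of the citric acid cycle, rose 6.88-fold (log2 2.78 ± 0.073, adjusted p = 6.2e-10) and the lipid droplet gene PLIN2 5.88-fold (log2 2.56 ± 0.12, adjusted p = 4.79e-07). Heme oxygenase 1 (HMOX1) rose 3.68-fold (log2 1.88 ± 0.13), NAB2 3.60-fold (log2 1.85 ± 0.096) and ZNF366 2.78-fold (log2 1.48 ± 0.13). FMR1 fell 3.07-fold (log2 -1.62 ± 0.31, adjusted p = 0.0036) and SERPINB2, a plasminogen activator inhibitor, 2.92-fold (log2 -1.55 ± 0.17). The kinase gene MAP2K6 fell 1.99-fold (log2 -0.99 ± 0.13), AKAP7 1.95-fold (log2 -0.97 ± 0.15) and the potassium channel gene KCNJ2 1.85-fold (log2 -0.89 ± 0.16). 20 of 29 tested ATF4 targets rose and 0 fell (24 and 0 adjusted over the list alone), with camera adjusted p = 1.11e-13, adjusted p = 0.191 with an estimated correlation. SLC7A5 rose 1.77-fold (log2 0.82 ± 0.058), SLC7A1 1.23-fold (log2 0.30 ± 0.035) and TRIB3 1.79-fold (log2 0.84 ± 0.10), with a highest adjusted p = 0.000162. Immediate early genes rose in 19 of 34 tested cases and fell in 0 (24 and 4 adjusted over the list alone), at camera adjusted p = 1.05e-09, adjusted p = 0.141 with an estimated correlation. EGR3 rose 4.39-fold (log2 2.13 ± 0.20), FOS 1.39-fold (log2 0.48 ± 0.054) and KLF10 1.32-fold (log2 0.40 ± 0.047), with a highest adjusted p = 0.000136.

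Among inflammatory genes, 14 of 28 tested rose and 0 fell (16 and 1 adjusted over the list alone), with camera adjusted p = 1.11e-08, adjusted p = 0.149 with an estimated correlation. RELB rose 2.25-fold (log2 1.17 ± 0.081), CD83 2.09-fold (log2 1.06 ± 0.079) and NFKBIA 1.42-fold (log2 0.50 ± 0.043), with a highest adjusted p = 1.69e-05. DNA replication genes numbered 35 in the test, of which 14 fell and 0 rose (22 and 0 adjusted over the list alone), at camera adjusted p = 9.02e-08, adjusted p = 0.27 with an estimated correlation. MCM7, a subunit of the replicative helicase, fell 1.12-fold (log2 -0.16 ± 0.029), RFC3 1.18-fold (log2 -0.24 ± 0.046) and MCM3 1.12-fold (log2 -0.16 ± 0.03), with a highest adjusted p = 0.00346. 13 of 24 tested cholesterol synthesis genes rose and 1 fell (17 and 1 adjusted over the list alone), with camera adjusted p = 9.02e-08, adjusted p = 0.361 with an estimated correlation. CYP51A1 rose 1.41-fold (log2 0.49 ± 0.049), with adjusted p = 4.21e-05. NRF2 targets and oxidative stress genes rose in 12 of 24 tested cases and fell in 0 (13 and 0 adjusted over the list alone), at camera adjusted p = 9.02e-08, adjusted p = 0.141 with an estimated correlation. ME1 rose 1.97-fold (log2 0.98 ± 0.048) and SQSTM1 1.80-fold (log2 0.85 ± 0.07), with a highest adjusted p = 1.4e-05. Among unfolded protein response genes, 8 of 20 tested fell and 1 rose (10 and 2 adjusted over the list alone), with camera adjusted p = 0.00445, adjusted p = 0.149 with an estimated correlation.

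CHX alone, the control for the combination, changed 10122 of the 15327 genes, 5138 higher and 4984 lower. BIRC3, an inhibitor of apoptosis induced by NF-kB, rose 31.1-fold (log2 4.96 ± 0.14, adjusted p = 8.39e-12) and the adhesion gene ICAM1 22.3-fold (log2 4.48 ± 0.064, adjusted p = 9.53e-14). Thrombospondin 1 (THBS1) rose 15.9-fold (log2 3.99 ± 0.23), LRRC37A2, which has near-identical copies, 9.30-fold (log2 3.22 ± 0.10) and RELB 8.75-fold (log2 3.13 ± 0.075). Cyclin E2 (CCNE2) fell 15.2-fold (log2 -3.93 ± 0.061, adjusted p = 1.36e-13) and ZNF367 6.66-fold (log2 -2.74 ± 0.069). The ribonucleotide reductase gene RRM2 fell 6.51-fold (log2 -2.70 ± 0.76), the chaperone gene HSPA8 6.21-fold (log2 -2.63 ± 0.028) and TBL1X 5.83-fold (log2 -2.54 ± 0.15). Ribosomal protein genes numbered 77 in the test, of which 75 fell and 0 rose (75 and 0 adjusted over the list alone), at camera adjusted p = 5.1e-21, adjusted p = 0.327 with an estimated correlation. RPL15 fell 1.94-fold (log2 -0.95 ± 0.032), RPL14 1.69-fold (log2 -0.76 ± 0.028) and RPL4 1.51-fold (log2 -0.60 ± 0.024), with a highest adjusted p = 2.04e-10. 33 of 42 tested nuclear genes of oxidative phosphorylation fell and 1 rose (33 and 1 adjusted over the list alone), with camera adjusted p = 1.66e-06, adjusted p = 0.327 with an estimated correlation. NDUFB9 fell 2.57-fold (log2 -1.36 ± 0.057), COX4I1 1.49-fold (log2 -0.58 ± 0.027) and COX5A 1.40-fold (log2 -0.49 ± 0.033), with a highest adjusted p = 2.39e-08.

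Ribosome biogenesis genes fell in 34 of 41 tested cases and rose in 4 (34 and 5 adjusted over the list alone), at camera adjusted p = 3.27e-06, adjusted p = 0.327 with an estimated correlation. UBTF fell 1.75-fold (log2 -0.81 ± 0.033), NOP56 1.88-fold (log2 -0.91 ± 0.038) and NOLC1 1.82-fold (log2 -0.86 ± 0.038), with a highest adjusted p = 5.2e-10. Among DNA replication genes, 27 of 35 tested fell and 4 rose (27 and 4 adjusted over the list alone), with camera adjusted p = 3.37e-06, adjusted p = 0.314 with an estimated correlation. CDT1 fell 3.61-fold (log2 -1.85 ± 0.048) and FEN1 3.68-fold (log2 -1.88 ± 0.055), with a highest adjusted p = 1.68e-11. Unfolded protein response genes numbered 20 in the test, of which 16 fell and 0 rose (16 and 0 adjusted over the list alone), at camera adjusted p = 1.27e-05, adjusted p = 0.0836 with an estimated correlation. SEL1L fell 1.75-fold (log2 -0.81 ± 0.022), CALR 1.88-fold (log2 -0.91 ± 0.031) and HSP90B1 1.57-fold (log2 -0.65 ± 0.027), with a highest adjusted p = 3.67e-10. 21 of 28 tested inflammatory genes rose and 1 fell (21 and 1 adjusted over the list alone), with camera adjusted p = 3.25e-05, adjusted p = 0.303 with an estimated correlation. NFKBIA, an inhibitor of NF-kB, rose 4.36-fold (log2 2.12 ± 0.042). Genes encoded by mitochondrial DNA fell in 13 of 13 tested cases and rose in 0 (13 and 0 adjusted over the list alone), at camera adjusted p = 3.37e-06, adjusted p = 0.33 with an estimated correlation. MT-ATP8 fell 1.81-fold (log2 -0.86 ± 0.04), MT-CO3 1.93-fold (log2 -0.95 ± 0.049) and MT-ND5 1.72-fold (log2 -0.79 ± 0.044), with a highest adjusted p = 4.53e-09.

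ML-60218 was also added under CHX, which asks what part of its response remains when translation is blocked. Against CHX alone, 2529 of the 15327 genes were called, 1341 higher and 1188 lower. There were 1644 calls without CHX plus ML-60218 replicate 3 and 1470 with the length offset. NGFR rose 9.90-fold (log2 3.31 ± 0.38, adjusted p = 0.000119) and EGR3 9.65-fold (log2 3.27 ± 0.17, adjusted p = 4.74e-07). FOSB rose 8.94-fold (log2 3.16 ± 0.19), RNF150 by log2 2.26 ± 0.23 and the nuclear receptor gene NR4A3 4.48-fold (log2 2.16 ± 0.17). GPR82 fell 1.89-fold (log2 -0.92 ± 0.13) and IRAG1 1.77-fold (log2 -0.82 ± 0.10). The histone methyltransferase gene SETD1A fell 2.32-fold (log2 -1.21 ± 0.28), a call lost at adjusted p = 0.112 with the length offset. For SETD1A the range over all alternatives was 0.00281 to 0.112. MAP2K6 fell 2.17-fold (log2 -1.12 ± 0.12), lost at adjusted p = 0.123 with the length offset. For MAP2K6 the range over all alternatives was 1.56e-15 to 0.123. SNAPC4, a subunit of the factor that drives small nuclear RNA genes, fell 2.04-fold (log2 -1.03 ± 0.26, adjusted p = 0.0168) and lost its call at adjusted p = 0.0508 to 0.0631 without CHX replicate 1 or 3 and CHX plus ML-60218 replicate 1 or 2. For SNAPC4 the range over all alternatives was 0.00159 to 0.0631. Among cholesterol synthesis genes, 20 of 24 tested rose and 0 fell (22 and 0 adjusted over the list alone), with camera adjusted p = 5.75e-21, adjusted p = 0.21 with an estimated correlation. SQLE rose 2.01-fold (log2 1.007 ± 0.052) and HMGCS1 2.10-fold (log2 1.07 ± 0.056), with a highest adjusted p = 4.74e-07.

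Immediate early genes numbered 34 in the test, of which 20 rose and 0 fell (23 and 0 adjusted over the list alone), at camera adjusted p = 6.1e-11, adjusted p = 0.205 with an estimated correlation, with EGR3 and FOSB among them. 13 of 28 tested inflammatory genes rose and 0 fell (16 and 1 adjusted over the list alone), with camera adjusted p = 1.24e-05, adjusted p = 0.3 with an estimated correlation. CD83 rose 2.44-fold (log2 1.29 ± 0.067), CCL5 1.51-fold (log2 0.59 ± 0.055) and NFKBIA by log2 0.32 ± 0.038, with a highest adjusted p = 0.000175. Ribosomal protein genes rose in 8 of 77 tested cases and fell in 0 (4 and 0 adjusted over the list alone), at camera adjusted p = 7.4e-07, adjusted p = 0.63 with an estimated correlation. RPL9 rose 1.17-fold (log2 0.23 ± 0.04) and RPS29 1.16-fold (log2 0.21 ± 0.042), with a highest adjusted p = 0.00486. Among lysosome and autophagy genes, 10 of 31 tested rose and 0 fell (10 and 0 adjusted over the list alone), with camera adjusted p = 0.000144, adjusted p = 0.477 with an estimated correlation. FNIP2 rose 1.46-fold (log2 0.55 ± 0.038), SQSTM1 1.67-fold (log2 0.74 ± 0.067) and RRAGD 1.49-fold (log2 0.57 ± 0.067), with a highest adjusted p = 0.000154. ATF4 targets numbered 29 in the test, of which 9 rose and 1 fell (9 and 2 adjusted over the list alone), at camera adjusted p = 0.123, adjusted p = 0.732 with an estimated correlation.

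The interaction tested whether the log2 fold change with ML-60218 differed between cells with and without CHX. Of 15327 genes, 1006 differed, 439 with a higher value under CHX and 567 with a lower one. The count was 620 without CHX replicate 1, 641 without CHX replicate 3, 648 without ML-60218 replicate 2 and 456 with the length offset. FOSB differed by 5.54-fold (log2 2.47 ± 0.30, adjusted p = 0.00105) and the cholesterol synthesis genes SQLE and HMGCS1 by 1.56-fold (log2 0.64 ± 0.072) and 1.63-fold (log2 0.70 ± 0.08), with higher values under CHX. Lower values under CHX were found for ZNF366, by 2.74-fold (log2 -1.46 ± 0.19, adjusted p = 0.00138), PLIN2, by 2.67-fold (log2 -1.42 ± 0.17), CLIP2, by 2.61-fold (log2 -1.38 ± 0.11), and SLAMF8, by 2.58-fold (log2 -1.37 ± 0.17). SETD1A differed by 3.22-fold (log2 -1.69 ± 0.38), a call lost at adjusted p = 0.236 with the length offset and 0.0542 to 0.0607 without CHX replicate 3 and DMSO replicate 2. For SETD1A the range over all alternatives was 0.00621 to 0.236. FMR1 differed by 3.80-fold (log2 1.93 ± 0.42), lost at adjusted p = 0.0505 to 0.0516 without CHX replicate 3 and ML-60218 replicate 2. For FMR1 the range over all alternatives was 0.00442 to 0.0516. RNF150 differed by 2.75-fold (log2 1.46 ± 0.35), lost at adjusted p = 0.12 with the length offset and 0.0537 to 0.0704 without CHX replicate 1 or 3, DMSO replicate 1 or 3 and ML-60218 replicate 1 or 3. For RNF150 the range over all alternatives was 0.000428 to 0.12. NR4A3 differed by 2.69-fold (log2 1.43 ± 0.34), lost at adjusted p = 0.0522 to 0.14 without CHX replicate 1, CHX plus ML-60218 replicate 2 or 3, DMSO replicate 2 and ML-60218 replicate 1 or 3. For NR4A3 the range over all alternatives was 0.000417 to 0.14. CAPN5 differed by 2.56-fold (log2 1.36 ± 0.33), lost at adjusted p = 0.0566 to 0.0801 without CHX replicate 1 or 3, DMSO replicate 1 or 2 or 3 and ML-60218 replicate 1 or 3. For CAPN5 the range over all alternatives was 0.000797 to 0.0801.

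11 of 24 tested cholesterol synthesis genes had a higher value under CHX and 1 a lower one (16 and 1 adjusted over the list alone), at camera adjusted p = 4.41e-11, adjusted p = 0.477 with an estimated correlation. INSIG1, which retains the SREBP activator in the endoplasmic reticulum, differed by 1.88-fold (log2 0.91 ± 0.10). 0 of 29 tested ATF4 targets had a higher value under CHX and 12 a lower one (1 and 13 adjusted over the list alone), at camera adjusted p = 7.29e-07, adjusted p = 0.477 with an estimated correlation. JDP2 differed by 1.73-fold (log2 -0.79 ± 0.13) and STC2 2.23-fold (log2 -1.16 ± 0.21), with a highest adjusted p = 0.00753. NRF2 targets and oxidative stress genes had a higher value under CHX in 0 cases and a lower one in 7, of 24 tested (0 and 9 adjusted over the list alone), at camera adjusted p = 6.42e-06, adjusted p = 0.228 with an estimated correlation. ME1 differed by 1.82-fold (log2 -0.86 ± 0.071), HMOX1 2.13-fold (log2 -1.09 ± 0.18) and SRXN1 1.36-fold (log2 -0.45 ± 0.088), with a highest adjusted p = 0.0115. Unfolded protein response genes had a higher value under CHX in 7 cases and a lower one in 0, of 20 tested (9 and 0 adjusted over the list alone), at camera adjusted p = 6.65e-05, adjusted p = 0.129 with an estimated correlation. HSPA5, the chaperone BiP, differed by 1.42-fold (log2 0.51 ± 0.051) and CALR 1.24-fold (log2 0.31 ± 0.044), with a highest adjusted p = 0.00209.

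Called in the same direction with ML-60218 in both settings were 866 of the 15327 genes, 478 higher and 388 lower, against 197 for independent lists, with 74 called in opposite directions against 195. The shared count was 395 at an adjusted p under 0.01 and 516 with the length offset. PDK4 rose 6.88-fold (log2 2.78 ± 0.073) without CHX and 4.23-fold (log2 2.08 ± 0.068) with it, and CPT1A, which imports fatty acids into mitochondria, 1.51-fold (log2 0.60 ± 0.033) and 1.42-fold (log2 0.51 ± 0.033). DBI, an acyl-CoA-binding protein gene, rose 1.45-fold (log2 0.53 ± 0.041) and 1.63-fold (log2 0.70 ± 0.041) and HAUS6 by log2 0.33 ± 0.022 and 1.26-fold (log2 0.33 ± 0.023). TXNIP, a thioredoxin-binding protein gene, fell 1.33-fold (log2 -0.41 ± 0.04) and 1.31-fold (log2 -0.39 ± 0.04) and METTL7A 1.57-fold (log2 -0.65 ± 0.052) and 1.56-fold (log2 -0.64 ± 0.049). The phosphatase gene PTPN18 fell 1.18-fold (log2 -0.23 ± 0.027) and by log2 -0.32 ± 0.027. Across 10146 genes, which are not independent replicates, the log2 fold changes of both comparisons had Pearson's r = 0.379 and Spearman's rho = 0.42.

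**Figure D3:**
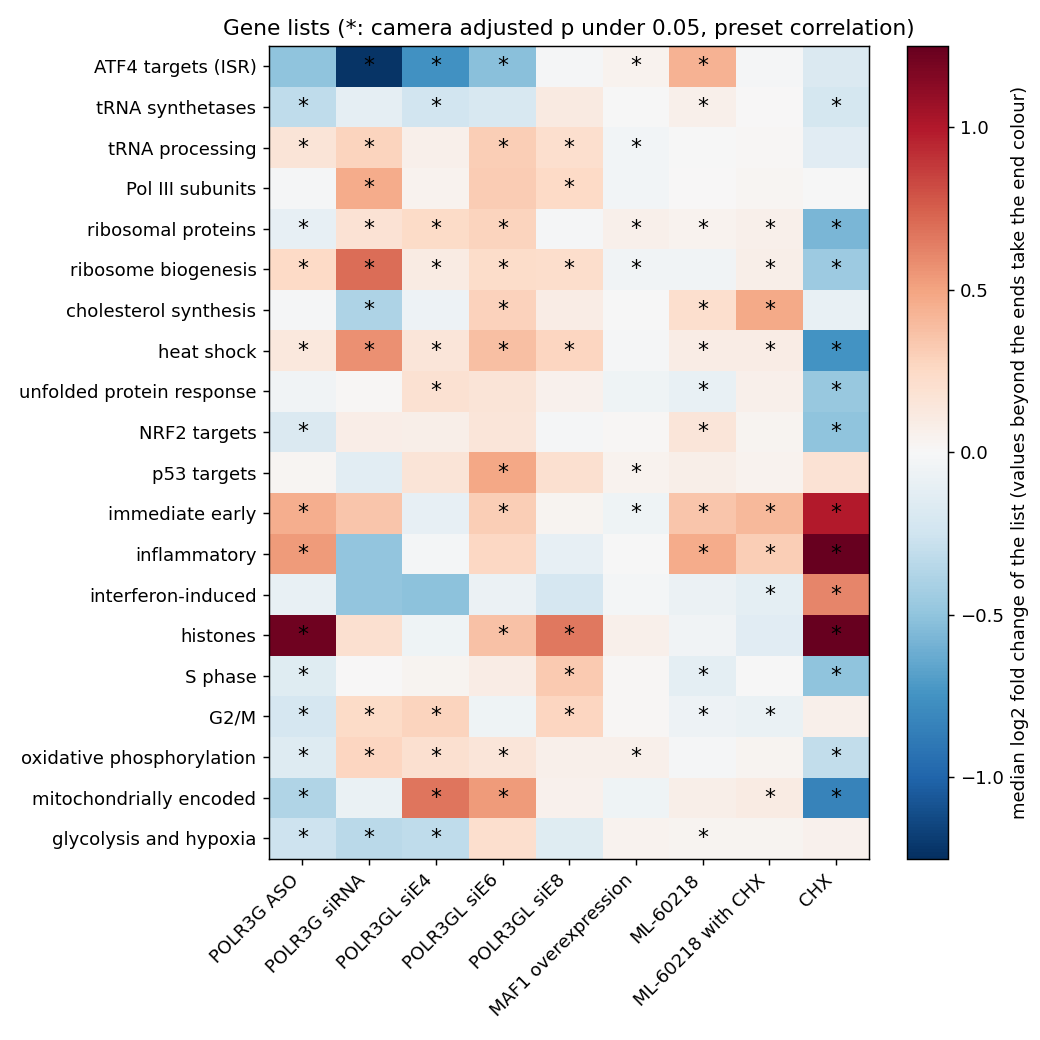
Heat map of the median log2 fold change of 20 gene lists (vertical axis) in 9 comparisons (horizontal axis), red for higher and blue for lower, with a star where camera's adjusted p with the preset correlation was under 0.05. The median of ATF4 targets was starred below 0 with the POLR3G siRNA, siE4 and siE6, starred above 0 with ML-60218 and MAF1 overexpression, and -0.50 without a star with the POLR3G ASO. None of the starred calls passed with an estimated correlation.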

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

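The tests of a seed in the control siRNA, of deeper sequencing, of lower POLR3G itself and of a MAF1 transcript that did not rise were chosen only after the result was seen. Effects under the same contrast differed between conditions by a direct test in 5 cases. The response to ML-60218 differed with CHX in 1006 genes, which 2 of 100 drawn splits of the libraries matched or exceeded, the real one included. The highest other split called 4118 genes. Relabelling the groups can mix the effects of CHX (10122 genes) and ML-60218 (2380) into a split, so these splits do not measure chance alone. The POLR3G ASO and siRNA differed in 11679 genes, which 1 of 100 drawn splits reached, the real one, with 7402 in the highest other, and this limit holds there too. The POLR3GL siRNAs differed from each other in 10085 genes (siE4 and siE6), 9806 (siE4 and siE8) and 9999 (siE6 and siE8), with 1 gene in the highest other split of each. Outside the genes tested, transcripts not matched to a gene took 9.497% ± 0.0586 of reads (SD, n = 3) with the POLR3G ASO, above 8.607% ± 0.0351 with the scrambled ASO.

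Comparisons of 3 libraries with 3 allow 10 splits, too few for a share under 0.05. In each, only the real split gave as many calls, except for MAF1 overexpression (2 of 10). The other splits mix both groups, so an effect widens their spread and their counts do not measure chance alone. Real counts and those of the highest other split were 11713 and 1 for the POLR3G ASO, 11551 and 0 for the POLR3G siRNA, 8553 and 2 for siE4, 9817 and 2 for siE6, 8985 and 1 for siE8, 6 and 6 for MAF1 overexpression, 2380 and 1 for ML-60218, 10122 and 0 for CHX, and 2529 and 3 for ML-60218 with CHX.

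The sets of genes that the siRNAs changed overlapped and differed in part. Sites in 3′ UTRs that pair with siRNA seeds are a candidate explanation that the values go with for part of the falls. Such sites lie in 12.6% (siE8), 30.2% (siE6), 6.3% (siE4) and 4.7% (POLR3G siRNA) of the searched genes called lower. Among all searched genes, 649 of 10982, 2240 of 10949, 435 of 10962 and 318 of 11016 hold them. Over all 7-mers, the lowest t was -24.5 for GCUAUCU with siE8, -17.3 for GAGGAAA with siE6, -9.9 for AACGUGG with siE4 and -9.6 for CCGCAGA with the POLR3G siRNA, beyond shuffled bounds of -6.24, -5.04, -5.64 and -5.29, and each 7-mer occurs in its siRNA's target, where 9.7% (POLR3GL) or 19.4% (POLR3G) of all 7-mers occur, while CCGCAGA occurs in MAF1 transcripts too. Passing such a bound does not by itself mark a seed, since with the POLR3G ASO, which has none, UUUUUAA (-5.3, bound -4.5) and GAGUUCA (7.0, bound 5.29) passed as well, though neither occurs in POLR3G. A seed of the control siRNA may add to this, since GACAGUA had the highest t with the POLR3G siRNA (8.7) and siE4 (11.3) and stood at 8.1 and 9.1 with siE6 and siE8. A graded effect of knockdown depth, which differed by at most 0.361 on the log2 scale (siE6 and siE8, adjusted p = 0.0401), is hard to set beside the 4441 genes called with all 3 POLR3GL siRNAs, of which 2303 share a direction, but protein was not measured and depth stays open, as does a response to lower POLR3GL that the siRNAs share (covariance at least 0.0566 above simulated unchanged groups).

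The POLR3G ASO libraries detected 23936 ± 39.9 genes against 20962 ± 142 with the scrambled ASO (SD, n = 3). Deeper sequencing is argued against, at 35 M reads at most against a control mean of 37.83 M. The POLR3G siRNA gave 0 more detected genes than its control (SD 172) but also lowered MAF1, so lower POLR3G stays open. Reads from genomic DNA or unspliced RNA may contribute, since olfactory receptor genes summed to 603.7 CPM against 190, with retained-intron transcripts at 5.624% against 4.994% of reads. Such RNA's source (cells or preparation) and part in the histone rise were not tested.

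MAF1 overexpression changed few genes. A MAF1 transcript that did not rise is argued against, since the lowest MAF1 library held 68.1 times the level of the highest eGFP library. Low power stays open for small changes, as 76% of simulated 1.5-fold changes were recovered in these libraries, and the level and activity of MAF1 protein were not measured.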

How the results depend on the processing

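The length offset, the minimum mean of 5 CPM, the removal of switching genes and the left-out libraries for same-direction counts were chosen only after the data were seen. Of 292 alternative values of 18 counts, 278 lay within 1.5 times the reported count. The exceptions were MAF1 overexpression, with 11 calls without a filter, 36 by DESeq2, 2 at a minimum of 5 CPM and 2 to 9 with a library left out, ML-60218, with 1520 to 2174 with a library left out, ML-60218 with CHX, with 1470 under the length offset and 1644 to 2289 with a library left out, the interaction, with 456 under the length offset and 620 to 1092 with a library left out, and the same-direction count of ML-60218, with 395 at an adjusted p under 0.01 and 516 under the length offset, with 628 to 798 when a library was left out. A stricter threshold lowers a count by construction, and for the others the cause was not tested. Camera's list calls, 18, 12, 11, 13, 7, 9, 14, 15, 12, 9 and 13 in the order ASO, POLR3G siRNA, siE4, siE6, siE8, MAF1, ML-60218, CHX, ML-60218 with CHX, interaction and ASO minus siRNA, became 0 with an estimated correlation in all but the last and 1 there.

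Of 5347 alternative values for named genes, 5230 kept direction and side of the threshold, 95 lost a call, 6 gained one and 16 changed sign, of which KMT2D with the POLR3G ASO (0.007 under the length offset) had been called. Uncalled values that changed sign were MAF1 with the POLR3G ASO (0.057) and MTHFD1L with MAF1 overexpression (0.019) under the length offset, and with a library left out LYSMD3 with MAF1 overexpression (-0.056 to 0.006), POLR3GL with ML-60218 under CHX (-0.049 to 0.011) and POLR3G in THP-1, with ranges of -0.77 to 0.86 for ML-60218, -1.08 to 0.26 for CHX, -0.25 to 0.73 for ML-60218 with CHX and -0.64 to 0.99 for the interaction, where about 1 CPM limits the estimate. The replicate numbers do not pair the samples, since same-numbered libraries correlated at -0.312 to 0.289 over 36 pairs of libraries. With the replicate block the counts were 11525 (POLR3G ASO), 11323 (POLR3G siRNA), 8440, 9710 and 8850 (siE4, siE6 and siE8), 6 (MAF1), 2389 (ML-60218), 10083 (CHX), 2469 (ML-60218 with CHX), 926 (interaction), 11285 (ASO minus siRNA), 9956, 9687 and 9903 between POLR3GL siRNAs, and 2241, 3425, 878 and 5067 for same-direction calls (POLR3GL, HEK293T, ML-60218 and POLR3G).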

Other observations

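The seed test on REST was run on the same data in which the pattern was seen. Lists around the Pol III system were counted in knockdowns where 54.9% to 74.9% of all genes tested were called. Of 18 subunit genes, those higher and lower were 14 and 3 with siE8 (14 and 3 adjusted over the list alone, camera adjusted p = 0.0447, adjusted p = 0.76 with an estimated correlation), 11 and 3 with siE6 (11 and 3 adjusted over the list alone, camera adjusted p = 0.0814, adjusted p = 0.719 with an estimated correlation), 8 and 7 with siE4 (8 and 7 adjusted over the list alone, camera adjusted p = 0.959, adjusted p = 0.968 with an estimated correlation) and 7 and 6 with the POLR3G ASO (7 and 6 adjusted over the list alone, camera adjusted p = 0.965, adjusted p = 0.99 with an estimated correlation). The targets POLR3G and POLR3GL are counted as lower in each. With siE4 (log2 -0.845 and -3.563 for these) the list's median was 0.043 but its mean -0.177. Among 20 tRNA synthetase genes they were 3 and 12 with siE4 (3 and 13 adjusted over the list alone, camera adjusted p = 0.0238, adjusted p = 0.852 with an estimated correlation), 4 and 13 with siE6 (4 and 13 adjusted over the list alone, camera adjusted p = 0.0556, adjusted p = 0.719 with an estimated correlation), 10 and 3 with siE8 (10 and 3 adjusted over the list alone, camera adjusted p = 0.226, adjusted p = 0.984 with an estimated correlation), 9 and 11 with the POLR3G siRNA (9 and 11 adjusted over the list alone, camera adjusted p = 0.627, adjusted p = 0.721 with an estimated correlation), 6 and 0 with ML-60218 (9 and 2 adjusted over the list alone, camera adjusted p = 0.0205, adjusted p = 0.51 with an estimated correlation) and 1 and 13 with CHX (1 and 13 adjusted over the list alone, camera adjusted p = 0.00681, adjusted p = 0.333 with an estimated correlation). In CHX poly(A) RNA, 19 of 21 histone genes rose and 0 fell (19 and 0 adjusted over the list alone). Of 33 interferon genes there, 19 rose and 4 fell (20 and 4 adjusted over the list alone). Camera gave adjusted p = 3.32e-05 and 0.0142 (each 0.303 with an estimated correlation). With ML-60218 under CHX, 1 interferon gene rose and 9 fell (1 and 10 adjusted over the list alone, camera adjusted p = 0.00349, adjusted p = 0.3 with an estimated correlation).

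A hypothesis is that SYP may have risen with the POLR3G siRNA and siE8 via lower REST, a repressor of neuronal genes. It was named after its values were seen, and no neuronal list was tested. REST fell with the POLR3G siRNA (log2 -1.15 ± 0.054, adjusted p = 9.96e-08) and siE8 (-1.11 ± 0.089, adjusted p = 2.2e-07), and of a list of 26 REST targets, 17 of 22 tested (77.3%) and 17 of 23 (73.9%) were called higher and 4 and 3 lower. Of all genes tested, 5674 of 15423 and 4530 of 15573 were higher. With siE4, where REST was at 0.13 (adjusted p = 0.232), 21.7% were higher, with siE6, where it was at -0.22 (adjusted p = 0.0404), 26.1%, and with the POLR3G ASO, where it was at 0.12 (adjusted p = 0.339), 52.0%, where 4084 and 4862 of 15573 and 5890 of 17098 of all genes were higher. The share with siE8 fell short of the bar set beforehand for both comparisons, the ASO value does not follow REST, and no experiment here changed REST alone, so the hypothesis stays open. The 7-mers of 0 of the 2 siRNAs occur in the 3′ UTR of REST, but other seed sites were not searched.

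A second hypothesis is that PDK4, PLIN2, CPT1A and DBI rose with ML-60218 as part of a group of PPAR nuclear receptor targets. Of 22 tested genes of a list of 25 that leaves these genes out, 11 were higher and 1 lower with ML-60218, against 1300 of 15327 genes higher among all tested, and 7 were higher and 0 lower with ML-60218 under CHX (31.8%), the latter short of the bar set beforehand. Of genes chosen after their values were seen, ACSL1 rose in both (log2 0.55 ± 0.047 and 0.46 ± 0.046), as did TNFRSF21 (0.68 ± 0.09 and 0.50 ± 0.087), while ANGPTL4 was at 0.65 (adjusted p = 0.486) and 2.04 (adjusted p = 0.0105). CHX alone raised 45.5% of the list and lowered 7 genes, CD36 and ACSL1 are also in other fixed lists, and the receptors' activity was not measured, so this stays open too.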
